A study of Columba livia with 12 samples.

How the data were processed

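Total RNA of the pectoral muscle was extracted with TriReagent and made into TruSeq RNA libraries, per the labels' protocols, 1 library for each of 12 birds. The authors deposited 1 file per library of whole-number counts per gene, not normalized. The submitters' processing notes name bcl2fastq 2.20, FastQC 0.11.5, STAR, HTSeq and DESeq2, without saying which step each served. The layout of the deposited count files, with 5 summary rows at the end, is that of HTSeq's counter. The genome build, the annotation, the strand setting and the read layout are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes may share reads, and how reads shared by near-identical copies of a gene were treated is known only from the summary rows.

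The summary rows name no gene and were left out of library sizes and tests. Reads outside annotated genes made up 18.5% to 22.2% of the reads in a file, reads without a unique place 4.56% to 6.25%, and reads overlapping more than 1 gene 0.17% to 0.35%. The other 2 summary rows were 0 in every library. Total counts over genes ranged from 13611534 to 29169918. Counts of reads are not counts of independent molecules, so the depth limits counting error only, and the spread between birds sets the precision of the group comparisons.

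Genes were identified in the files by locus tags, and 0 of the 15392 tags matched any identifier in the gene table used here, which lists 22830 genes of another assembly of the species and carries no locus tags. The 36 gene lists fixed before the data were examined (metabolic and stress pathways, fibre types and markers of other cell types) could therefore not be tested, and no gene was named from the order of the tags. The rule for the genes in the text was to take those with the largest log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 1 CPM and complete separation of the groups. Its condition of a gene symbol could not be applied, and 2 tags per direction are given, out of 100 higher and 102 lower genes that met the rest.

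Groups were taken from the labels. The 7 trained and 5 untrained libraries were compared with edgeR 4.0.16 in R 4.3.3: low counts were filtered with filterByExpr, libraries scaled with TMM, dispersions estimated robustly, and the quasi-likelihood F test applied two-sided with Benjamini-Hochberg adjustment over 11047 genes and a threshold of 0.05. CPM values are TMM-scaled. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. Library numbers are not shared between the groups, so no pairing was fitted, and the labels give no batch. Principal components were computed on log2 CPM with a prior count of 2, and each was oriented so that trained birds had the higher mean. Single values were compared with an exact permutation test over all 792 assignments of the birds, two-sided, with Benjamini-Hochberg adjustment over a family of 8. No 2 libraries of a group were one library deposited again: over genes with at least 20 counts in a pair, the chi-square per degree of freedom of the 31 pairs within groups was at least 63.2, where sampling noise alone gives about 1.

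The test was tried on simulated data with 200 of the genes changed, drawn from the means, dispersions and library sizes of this comparison. Of 100 genes changed 2-fold it called 14, of 100 changed 4-fold it called 82, and it called 4 unchanged genes, with 10950 genes tested in all. Changes of 2-fold or less are therefore often missed in such data. Simulated counts were drawn independently for each gene and bird, with no bird standing apart in many genes at once. The rates need not hold in the real libraries. The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom 3.58.1 with sample weights, other scalings, other filters, other thresholds, 1 surrogate variable from sva 3.50.0, non-robust dispersions and leaving out each library in turn. Leaving out untrained bird 5 and trained bird 13 together, and blocks of 40 or 30 genes for the order of the tags, were chosen after the data were seen. Components, positions between the groups and a first edgeR run had been looked at before the final analyses were written. The blocks had first been explored with 50 genes and with overlapping windows of 40 genes, in which more windows shared the leading profile, and these explorations were not kept as results. The rule that would have accepted sex as an explanation was completed after its result was seen, which left the outcome unchanged. The rule for a mixed sample was also extended after its result was seen, by the share of reads without a unique place, which turned a mixture in untrained bird 5 from argued against to open.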

Results

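RNA was sequenced from the pectoral muscle, the main flight muscle, of 12 racing pigeons (Columba livia), with 1 library per bird. The trained group comprised 7 birds that had undergone flight training and were sampled after a 300 km race. The untrained group comprised 5 adult birds of the same loft that had never been trained for racing. The comparison asks how gene expression in the working muscle of trained, raced birds differs from that of untrained birds. Training, the race, basketing and transport went together in the trained group, so their effects were not separable in this design. Birds are named here by group and library number. The counts assigned to genes ranged from 13611534 in trained bird 13 to 29169918 in untrained bird 3. Their mean was 19601000 ± 4906900 (SD, n = 7) in trained and 20565000 ± 4941200 (SD, n = 5) in untrained birds, which did not differ (exact permutation test, two-sided, p = 0.739). Of 15392 genes in the files, 14484 had at least 1 count and 11047 had enough counts to be tested. Genes carried locus tags, none of which matched the gene table used here, so the files do not pair them with gene names, and genes are described here by level and direction.

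In trained birds 713 genes differed from untrained birds at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), which was 6.5% of the genes tested. Of these, 329 genes were higher in trained birds, with a median log2 fold change of 1.36, and 384 were lower, with a median of -1.6. Most called changes exceeded 2-fold, in 245 of the higher and 326 of the lower genes. The test favours large changes, since in simulated data without outlying birds it called 14 of 100 genes changed 2-fold and 82 of 100 changed 4-fold. The sizes of the called changes therefore do not describe all changes. Changes of more than 8-fold were found in 37 higher and 31 lower genes. Higher and lower calls were spread unevenly over classes of abundance. With the genes tested divided by mean abundance into 4 classes of near-equal size, the most abundant class had a median of 116 CPM (counts scaled to library size), and in it 138 called genes were higher and 104 were lower in trained birds. In the least abundant class, with a median of 1.79 CPM, 53 were higher and 76 were lower. The classes between them had 53 higher and 118 lower genes at a median of 9.94 CPM, and 85 and 86 at 31.1 CPM, so the balance did not rise evenly with abundance. The direction of the calls differed between the least and the most abundant class (Fisher's exact test, two-sided, odds ratio 1.9, p = 0.00449). This test was chosen after the counts were seen and treats genes as independent. Abundance was the mean over all 12 libraries, so a gene's own rise or fall in trained birds moved its abundance the same way. The test therefore cannot show a link between direction and abundance apart from the change itself. Among the 100 most abundant genes, 3 rose and 5 fell. All 7 trained birds lay above all 5 untrained birds in 144 genes and below all of them in 158. Chance gives such separation in 0.25% of genes on average, or 27.9 genes. Genes vary together, so the number by chance can lie far from this average, and its spread was not computed. Of these separated genes, 210 were among the calls.

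The number of calls depended on single birds. It was 197, 150, 111 and 111 without untrained birds 12, 2, 3 and 4, with 52, 40, 26 and 23 genes higher and 145, 110, 85 and 88 lower in trained birds. It was 1896 without untrained bird 5, with 1095 higher and 801 lower. The share of higher genes among the calls, 46.1% with all libraries, thus ranged from 20.7% to 57.8% with 1 library left out. It was 460, 236, 1120, 448, 426 and 421 without trained birds 10, 11, 13, 6, 8 and 9, and 580 without trained bird 7. Without both untrained bird 5 and trained bird 13, an analysis chosen after the data were seen, 2977 genes were called, 1602 higher and 1375 lower. All 713 genes were called again when untrained bird 5 was left out, and also when both birds were left out.

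**Figure D1:**
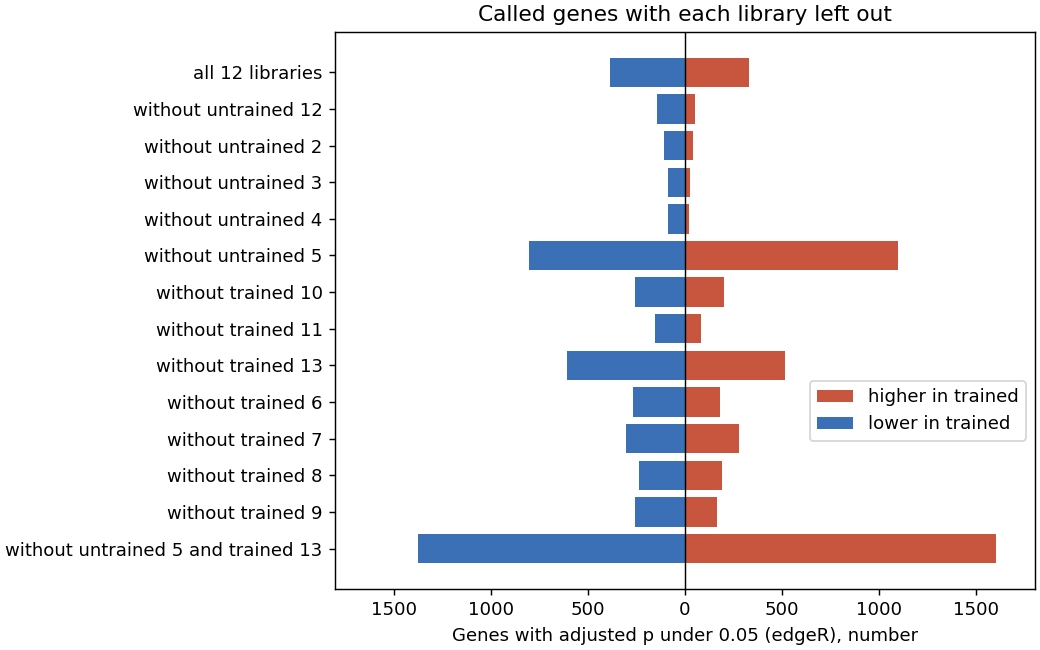
Number of genes with an adjusted p under 0.05 (x axis, edgeR), higher in trained birds to the right and lower to the left, with all 12 libraries and with the libraries on the y axis left out. The count of 713 with all libraries rose to 1896 without untrained bird 5 and fell to 111 without untrained bird 3 or 4.

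Locus tags A306_00003205 and A306_00006367 had the largest falls among called genes with a mean of at least 1 CPM that separated the groups fully. A306_00003205 was at 10.5 ± 5.35 CPM (SD, n = 7) in trained and 208 ± 110 CPM (SD, n = 5) in untrained birds, a log2 fold change of -4.31 ± 0.61 (SE) with an adjusted p of 0.0101 (edgeR). Untrained bird 5 had 20.2 CPM of it, close to the highest trained bird at 15.3 CPM, while the other untrained birds had 227 to 313 CPM. A306_00006367 was at 1.44 ± 0.883 CPM (SD, n = 7) in trained and 24 ± 20.6 CPM (SD, n = 5) in untrained birds, a log2 fold change of -4.03 ± 0.6 (SE) with an adjusted p of 0.0101 (edgeR). Untrained bird 5 again lay next to the trained birds, at 3.47 CPM against a highest trained value of 2.98 CPM and a lowest value of 14.6 CPM in the other untrained birds. Without untrained bird 12, which had 58.3 CPM, the log2 fold change of A306_00006367 was -3.4.

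Locus tags A306_00013790 and A306_00009404 had the largest rises under the same rule, and both were close to the detection floor in untrained birds. A306_00013790 was at 6.99 ± 9.51 CPM (SD, n = 7) in trained and 0.121 ± 0.204 CPM (SD, n = 5) in untrained birds, a log2 fold change of 5.75 ± 1.24 (SE) with an adjusted p of 0.0202 (edgeR). It had 1125 counts over the trained and 13 counts over the untrained libraries, and 10 of the 13 were in untrained bird 5. Its trained values spread from 0.883 to 25.5 CPM. A306_00009404 was at 1.8 ± 2.05 CPM (SD, n = 7) in trained and 0.0454 ± 0.0468 CPM (SD, n = 5) in untrained birds, a log2 fold change of 5.08 ± 0.99 (SE) with an adjusted p of 0.0161 (edgeR). Untrained bird 5 lay with the untrained birds in this gene, at 1 count and 0.0481 CPM against a lowest trained value of 0.312 CPM. The rule required full separation, so untrained bird 5 could not lie inside the trained range in any tag it chose. A306_00009404 rested on 265 trained and 5 untrained counts, and trained bird 9 held 161 of the 265. The sizes of both rises are therefore uncertain. A306_00013790 was not called without untrained bird 12, 2, 3 or 4 (adjusted p up to 0.069, edgeR), where its log2 fold change stayed at 5.46 to 5.59. That value was 7.41 without untrained bird 5 and 4.92 without trained bird 9, which held 670 of the 1125 trained counts. A306_00009404 was not called without untrained bird 3 or 4 (adjusted p up to 0.052, edgeR), where its log2 fold change was 5.29 and 4.82. Without trained bird 11, 13, 6, 8 or 9 it fell below the count filter and was not tested.

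**Figure D2:**
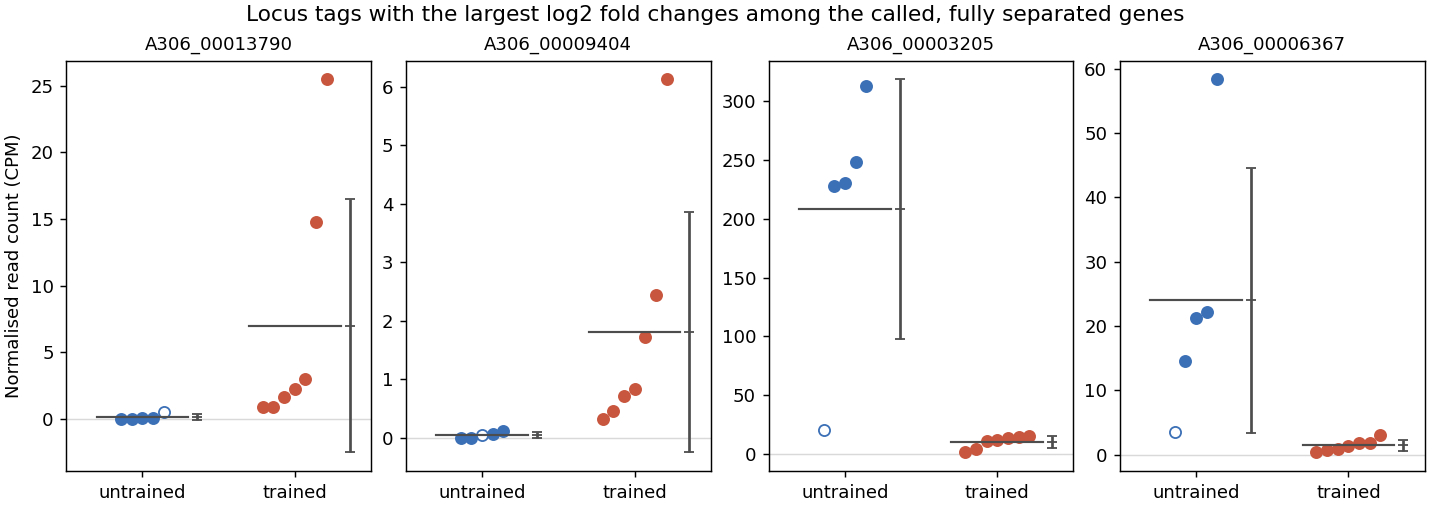
Normalised read count (CPM, linear y axes that differ between panels) of 4 locus tags in 5 untrained (blue) and 7 trained (red) birds. Horizontal lines are group means, vertical bars the SD, points single birds sorted by value, and the open circle is untrained bird 5, which had 20.2 CPM of A306_00003205 where the other untrained birds had at least 227 CPM.

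Over all genes tested, the birds formed 3 arrangements on the first 2 principal components, which held 34.6% and 27.3% of the variance. Untrained birds 2, 3, 4 and 12 lay together, with component 1 scores of -60.1 to -32.2. Trained bird 13 lay alone at 130.8. Untrained bird 5 lay at -2 on component 1 and 30.7 on component 2, among the trained birds. Component 1 was higher in trained birds by 65.9 (mean 27.4 ± 48.6, SD, n = 7, against -38.4 ± 22.7, SD, n = 5; exact permutation test, two-sided, p = 0.00758, adjusted p = 0.0202 over 8 measures). The sign of a component is arbitrary and was set so that trained birds had the higher mean. Only the size of the difference was therefore tested. The component was computed anew for each left-out bird, and the exact permutation p was 0.17, 0.118 and 0.121 without untrained bird 2, 3 and 4.

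**Figure D3:**
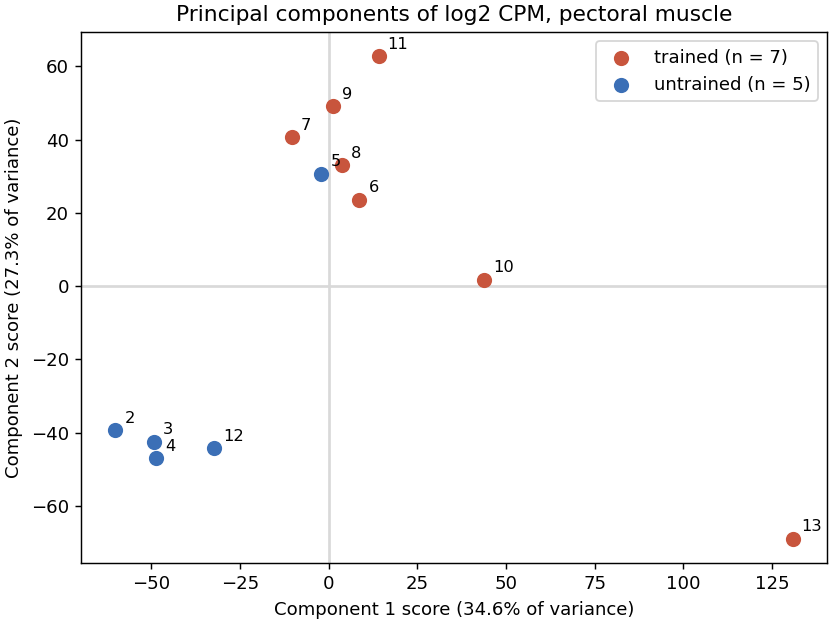
Scores on components 1 and 2 (34.6% and 27.3% of the variance, unitless scores of log2 CPM) of 7 trained and 5 untrained birds, each point 1 bird with its library number. Untrained bird 5 lies among the trained birds, and trained bird 13 lies apart at 130.8 on component 1.

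The rank correlations, taken across genes, also placed untrained bird 5 nearer to the trained birds. Untrained bird 5 had a median Spearman correlation of 0.964 with trained and 0.929 with untrained birds, whereas untrained birds 2, 3, 4 and 12 had 0.907 to 0.917 with trained and 0.959 to 0.972 with untrained birds. In a measure defined after the components were seen, each bird was placed on the axis from the untrained mean (0) to the trained mean (1), with both means taken without that bird and without untrained bird 5. Trained birds lay between 0.75 and 1.09, and untrained birds 2, 3, 4 and 12 between 0.04 and 0.24. Untrained bird 5 lay at 0.81. In trained bird 13, 11655 genes were detected, against 12546 to 13206 in the other trained birds.

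Reads that the counter did not assign to a gene also differed between the groups. Reads without a unique place in the genome were 4.85% ± 0.171 (SD, n = 7) of the reads in trained and 5.79% ± 0.35 (SD, n = 5) in untrained birds, with all 7 trained birds below all untrained birds, untrained bird 5 at 5.39% included (exact permutation test, two-sided, p = 0.00126, the smallest this design allows; adjusted p = 0.0101). Reads that overlapped more than 1 gene were 0.224% ± 0.0345 (SD, n = 7) and 0.298% ± 0.0369 (SD, n = 5) (exact permutation test, two-sided, p = 0.00758, adjusted p = 0.0202). Reads outside annotated genes were 20.4% ± 1.05 (SD, n = 7) and 19.1% ± 0.57 (SD, n = 5), a difference that did not pass the correction (exact permutation test, two-sided, p = 0.0253, adjusted p = 0.0506). The 10 most abundant genes held 13.9% ± 1.65 (SD, n = 7) of the counts in trained and 15.4% ± 1.82 (SD, n = 5) in untrained birds (exact permutation test, two-sided, p = 0.181, adjusted p = 0.241). Without trained bird 13 the exact p of that difference was 0.0325.

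**Figure D4:**
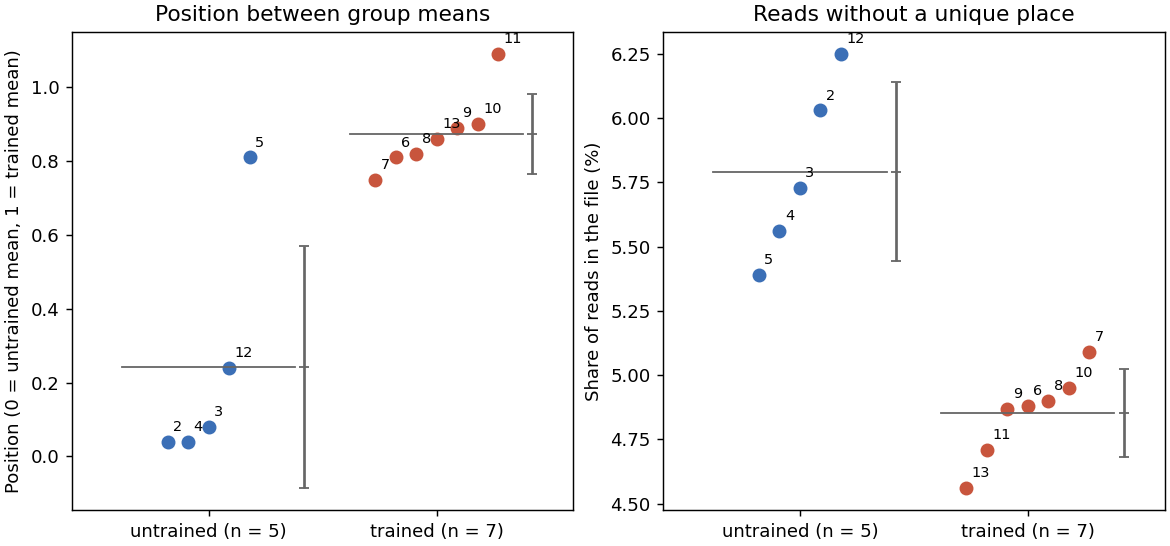
Left, position of each bird between the group means of log2 CPM (0 is the untrained and 1 the trained mean, each without the bird itself and without untrained bird 5). Right, reads without a unique place (% of the reads in the file). Points are single birds sorted by value with their library numbers, lines group means and bars the SD of 5 untrained and 7 trained birds. Untrained bird 5 sits at 0.81 on the left, and all trained birds lie below all untrained birds on the right.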

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

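The tests of a swap, of a single wrong label, of lower depth and of base composition were chosen after the result was seen, as was the use of reads without a unique place in weighing a mixed sample; those of a few abundant genes and of other splits were chosen before their own results were known. An extreme-value test of 16 measures in each group, some of them defined after the birds had been compared, picked out 10 values, and 8 of the 10 belong to untrained bird 5 or trained bird 13.

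Untrained bird 5 stood apart from the other untrained birds on component 2 (30.72 against at most -39.16), in its position between the groups (0.8098 against at most 0.2411), in its median correlation with trained birds (0.9638 against at most 0.9174) and in A306_00003205 (4.345 on the log2 CPM scale against at least 7.83). The library shares were divided. Reads overlapping more than 1 gene placed untrained bird 5 with the trained birds (0.249%, trained birds 0.174% to 0.271%, other untrained birds 0.293% to 0.353%). The 50 most abundant genes held 27.95% of its counts, within the range of trained birds without bird 13 (26.07% to 28.39%). The other untrained birds had 31.5% to 32.31%, but so did trained bird 13, at 32.2%, so this share did not separate the groups fully. Reads without a unique place (5.39%) lay between the highest trained bird at 5.09% and the lowest of the other untrained birds at 5.56%. Reads outside genes (19.03%) lay within the ranges of both groups. A swap with a trained bird is argued against, since the lowest trained position was 0.75. A single wrong label would place it among the trained birds, as its position of 0.81 does and its 5.39% does not, so it remains a candidate explanation with values on both sides. A mixture with mostly trained RNA cannot be told apart from it. Over genes called without this bird, its median CPM position was 0.74 for the higher and 0.95 for the lower genes. Both lay inside the trained ranges of 0.58 to 1.31 and 0.94 to 1.09, as set beforehand for no mixture. Trained birds 6, 7 and 9 had 0.94, 0.95 and 0.94 in the lower genes, so 0.95 did not set untrained bird 5 apart from them. Its 5.39% lay between the groups, but its position in the lower genes leaves little room for untrained RNA. A biological difference of this bird, such as unrecorded flight, was not tested.

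Trained bird 13 stood apart from the other trained birds on component 1 (130.8 against at most 43.8), in its TMM factor (0.7522 against at least 1.005), in the genes detected (11655 against at least 12546) and in its median correlation with trained birds (0.8613 against at least 0.9337). Lower depth is argued against as the whole cause, since with every library thinned to its depth 11655 genes were detected in it against 12461 to 12859 in the others. A few abundant genes are argued against too, since without the 50 most abundant genes its median correlation with trained birds was 0.859, against 0.933 to 0.962 in the other trained birds. Base composition, gene length or RNA quality may be involved and cannot be told apart from biology without gene sequences. Its block medians over 40 genes with consecutive locus tags reached 0.89 (log2), against at most 0.74 in 100 random orders of the genes, which only 2 of 177 blocks exceeded.

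Untrained bird 3 was picked out for its total of 29169918 counts, against at most 20302677 in the other untrained birds, and for its TMM factor of 0.9795, against at least 1.02. Reads outside genes, which enter no test of genes, were higher in trained birds by 1.33 percentage points and above the highest untrained bird in 6 of 7 trained birds.

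Other splits of the 12 libraries into 7 and 5 were tested for the count of called genes. Of 100 splits, the real one included, 2 called as many genes as the real one with 713, which argues against a chance split. The other was a split that exchanged untrained bird 5 with trained bird 9, with 743 calls. No further drawn split called more than 1 gene.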

How the results depend on the processing

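The direction of the 4 locus tags in the text held in every alternative that tested them. Their choice for full separation and large changes made this nearly certain, so it is no separate support. The count of 713 called genes stayed within 1.5 times, at 571 to 728, under DESeq2's size factors, total counts alone, library sizes without the 10 most abundant genes, both other count filters, non-robust dispersions and an added 2-fold minimum. It was 1691 with DESeq2 (889 higher, 802 lower), 3601 with limma-voom and sample weights, and 1404 with 1 surrogate variable, which mostly took up trained bird 13 (score 0.85). The sample weights of limma-voom were lowest for trained bird 13 (0.149) and untrained bird 5 (0.402), so that fit counted these birds least. The DESeq2 and surrogate-variable calls held all 713 genes and those of limma-voom 708. A similar count did not always mean the same genes. Of the 713, 553 were called with total counts alone and 582 with no count filter. The stricter filter, which tested 8275 genes, called 557 of them. DESeq2's size factors kept 704, library sizes without the 10 most abundant genes 708, and non-robust dispersions all 713. At an adjusted p under 0.01 edgeR called 0 genes, with a lowest adjusted p of 0.0101, 811 with DESeq2 and 1850 with limma-voom, while 2737 had an unadjusted p under 0.05 in edgeR. Leaving out 1 library gave 111 to 1896 calls, of which 20.7% to 57.8% were higher in trained birds, and leaving out untrained bird 5 and trained bird 13 together, chosen after the data were seen, gave 2977. With 1 library left out, the component 1 difference ranged from 39.4 to 80.1. Component 1 was computed and oriented anew each time, so this difference could not be negative. The difference in total counts ranged from -2177400 to 1186300. The difference in the share of the 10 most abundant genes ranged from -1.99 to -0.734 percentage points. The 50 most abundant genes gave a difference in share of -3.14 percentage points (exact permutation test, two-sided, p = 0.0354). Leaving out a library changes both the number of birds and which birds remain. The cause of these changes was not tested. No paired analysis was possible because the groups share no library numbers, and the planned gene list tests were not run because no tag matched a gene name.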

Other observations

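All tests in this part but that of a library-wide trend were chosen after the result was seen. Genes with neighbouring locus tags had a weak tendency to change alike between the groups. Over 8503 pairs of tested genes with consecutive tag numbers, the log2 fold changes had a Spearman correlation of 0.186 across pairs, against at most 0.039 in absolute value in 1000 shuffled orders. Whether consecutive tags are neighbours in the genome was not checked here.

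A second pattern of neighbouring tags followed neither group. Among 177 blocks of 40 genes with consecutive tags, ordered by tag number and taken without trained bird 13, the block medians of the leading block had an SD between birds of 0.34 (log2), against at most 0.209 in 100 random orders of the genes, which argues against a chance order. In this block untrained birds 2 and 4 and trained birds 7 and 8 lay at -0.56 to -0.43 (log2) and the other 7 birds at 0.02 to 0.31. With trained bird 13 included, that bird lay at -0.12. There was 1 other block with the same profile (r over 0.85) beyond the random orders, and with blocks of 30 genes there were 3 in all. The sex of the birds, through genes on a sex chromosome, is a candidate explanation. Only the block profiles were examined for it, without an annotation, and they do not tell it apart from others. A library-wide technical trend stays open as well, with r = 0.34 between the block and the share of reads outside genes over 11 birds, and only 1 of the 80 genes in both blocks was among the 713 calls.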
